A study of Macaca mulatta with 12 samples.

How the data were processed

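RNA of the dorsal raphe was compared between 12 female rhesus monkeys, 3 in each of 4 groups (placebo, estrogen, progesterone, estrogen plus progesterone). Per the labels, Silastic capsules with crystalline steroid were implanted under the skin for 1 month, total RNA was extracted with Trizol and purified on RNeasy columns, biotin was attached with an Enzo kit, and each chip stands for 1 monkey. Groups and replicate numbers were taken from the labels. The titles of the placebo arrays carry the code OVX, read here as ovariectomized. The titles of the other groups carry no such code. The titles of the progesterone arrays name progesterone but carry the code EP, while their descriptions carry P; they were taken as progesterone alone. The deposited values are intensity on a linear scale, 1 per probe set of an Affymetrix rhesus array, and the authors had scaled each array to a common level: the mean after removal of the lowest and highest 2% was 200.0 on every array. The software that made them is not given in the sources used here. Genomic positions were not used.

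Of 52865 probe sets, 99 controls were removed. The remaining 52766 were set to a floor at the 5th percentile of all values (intensity 4.96), log2 transformed and, since array medians spanned 6.15 to 6.62 and so differed by more than 0.15, quantile normalized. The 26383 probe sets whose mean over all arrays reached the median of these means (log2 6.31, intensity 79.5) were tested. Gene names came from the rhesus gene table: 24956 probe sets matched 1 symbol (15938 of those tested), 361 several (224) and 27449 none (10221). Probe sets with several symbols, none, or a locus number for a symbol (918 of those tested) were counted but not named.

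Each probe set was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 1 mean per group over all 12 arrays (8 residual and 3.54 prior degrees of freedom). The labels give replicate numbers 1 to 3 in each group but 1 monkey per chip, and name no shared batch or day. From the data alone, the numbers were taken to pair the arrays of estrogen plus progesterone with those of placebo and of estrogen, since the deviations from the group means of the same-numbered arrays correlated by 0.103 to 0.274 and by 0.142 to 0.507. All 6 values exceeded the limit of 0.1. The numbers were not taken to pair any other groups compared. This rule does not show pairing, since some unlike-numbered pairs exceeded the limit too. Over all groups the median correlation was 0.027 in the 18 same-numbered pairs and 0.012 in the 36 others. The reported fit has no block. The contrasts were estrogen, estrogen plus progesterone and progesterone against placebo; estrogen plus progesterone against each hormone alone; the main effect of each hormone; their interaction; and a moderated F test. Tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. The SE of a difference is that of the limma fit, and values per group are given with their SD. With 3 animals against 3, an exact permutation test of 1 gene cannot go below p = 0.1, so single genes rest on the limma model. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

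The groups, contrasts, threshold, gene lists, other settings and rule for named genes were fixed before the data were examined. In each comparison with placebo the rule took the 10 largest rises and 10 largest falls among genes past the threshold whose 3 treated arrays all lay outside the placebo range, filled where fewer passed by the lowest p, and also TPH2, SLC6A4, MAOA, MAOB, HTR1A, PGR, ESR1, ESR2 and FKBP5 on their brightest probe set. In the other contrasts it took the 5 lowest p in each direction (for the F test, which has no direction, the 5 lowest), and up to 4 members of each list that passed. USP16 and EXTL2 in progesterone against placebo, and SLC18A2, FEV, GATA2, GATA3, UCN, SLC17A8, CBLN1, FAT2 and PCP2, fell outside it and were chosen after their values were seen.

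Gene lists, 36 of pathways and cell types, were tested with limma camera at a preset correlation of 0.01 on the brightest probe set of each of 9959 genes, adjusted over the 35 lists with at least 3 measured genes, and again with an estimated correlation and with fry.

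The steps were tested on simulated data for progesterone against placebo with 26383 probe sets: of 50 changed at each size, 40.0% were recovered at a log2 change of 1, 82.0% at 1.5, 98.0% at 2 and 98.0% at 3, and 10 of 169 calls were false (5.92%). A list shifted by 0.3 among 9959 simulated genes ranked first, and 0 other lists passed. The simulated noise was independent between probe sets and between arrays, so neither correlated genes nor arrays that stand apart were simulated. The share of false calls and the count of other lists therefore need not hold in the real data.

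Other settings, chosen beforehand, were median alignment without quantile normalization, no filter or one at the 75th percentile, a floor at the 25th percentile, an intensity trend with robust variances, array weights, the replicate number as a block, the mean of the oligodendrocyte and myelin list as a covariate, 1 probe set per gene, only the 2 groups compared, and leaving out each array in turn. Leaving out the 3 arrays that stand apart on the first principal component, or fitting them as a block, was chosen after seeing the data, as was the fit on the 9 arrays without the progesterone group, with and without the replicate block. Regroupings of the arrays within each replicate number were also chosen after seeing the data. All 12 arrays were kept in the reported values.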

Results

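Gene expression was measured with an Affymetrix rhesus array in the dorsal raphe, the midbrain region that holds many of the brain's serotonin neurons, of 12 female rhesus monkeys. Each array came from 1 monkey. The 4 groups of 3 animals carried subcutaneous implants for 1 month with placebo, estrogen, progesterone, or estrogen plus progesterone, so the series asks what each ovarian hormone, alone and together, does to gene expression in this region. The titles of the placebo arrays carry the code OVX, read here as ovariectomized, so the placebo animals were not taken as intact females. The titles of the progesterone arrays carry the code EP and their descriptions the code P, and they were taken as progesterone alone. The median intensity of an array lay between 71.1 and 98.6. Rank correlations between pairs of arrays lay between 0.863 and 0.954, and no 2 arrays were identical. Arrays give no read depth, so the number of animals limits the precision: the 95% confidence interval of a log2 difference between 2 groups extended a median of 0.49 to each side.

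The arrays separated only in part by treatment. On the first principal component, which held 23.5% of the variance, the first arrays of the placebo, estrogen and estrogen plus progesterone groups lay at -51.6, -44.9 and -44.0, while the other 9 arrays lay between -1.64 and 29.0. On the second component (17.2%) the 3 progesterone arrays lay at -14.1, -46.3 and -54.5, below all 9 other arrays, which lay between 0.498 and 20.4. A control transcript of the array, EF1A, had a 3′ minus 5′ log2 signal of -0.37 to -0.31 in the 3 progesterone arrays and of -0.08 to 0.74 in the other 9.

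**Figure D1:**
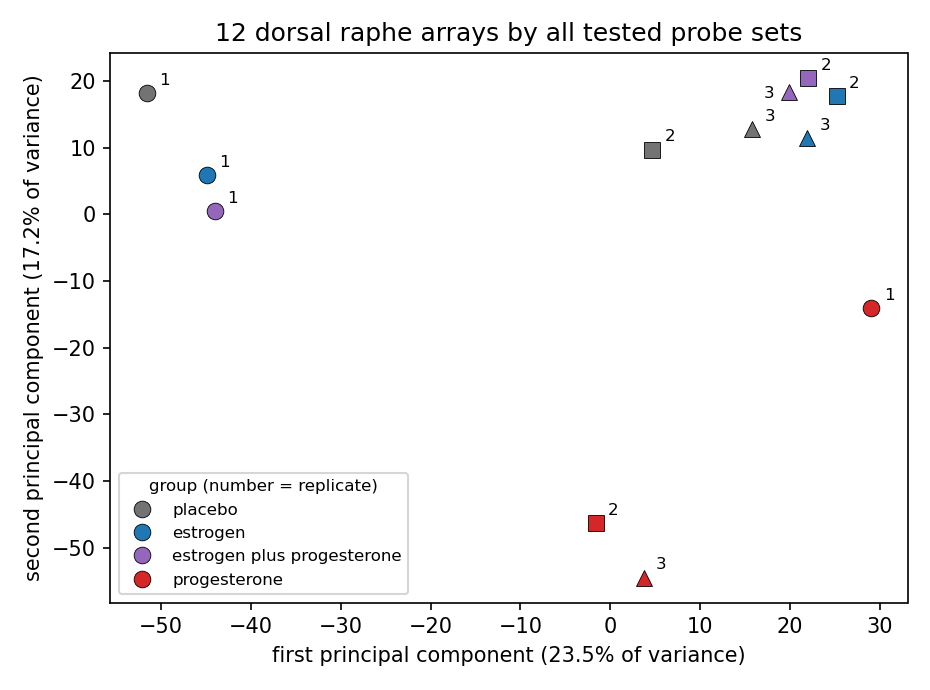
The 12 arrays on their first 2 principal components, computed from normalized log2 intensity, with 1 point per monkey colored by treatment and numbered by replicate. The first arrays of 3 groups lie between -51.6 and -44.0 on the first component, and the 3 progesterone arrays lie lowest on the second.

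The genes of the serotonin system showed no change that passed the test in any comparison with placebo. TPH2, the rate-limiting enzyme of serotonin synthesis in the brain, had a log2 intensity of 7.24 ± 0.69 (SD, n = 3) under placebo, 7.25 ± 0.13 under estrogen, 8.30 ± 0.68 under estrogen plus progesterone and 6.47 ± 1.61 under progesterone. The log2 differences from placebo were 0.01, 1.06 and -0.77 (SE 0.65), with 95% confidence intervals from -1.41 to 1.44, from -0.36 to 2.49 and from -2.19 to 0.65. The third progesterone array, at 4.66, decided the progesterone value: without it the difference was 0.13. MAOA, which breaks down serotonin and other monoamines, differed from placebo by 0.35, 0.07 and -0.06 (SE 0.20), and ESR2, the estrogen receptor beta gene, by 0.16, 0.34 and 0.15 (SE 0.31). Single arrays moved these values too: the combined treatment's TPH2 difference was 0.68 without the first placebo array, its ESR2 difference was 0.15 without the third placebo array and 0.58 without its second array, and MAOA under estrogen was 0.18 without the third estrogen array. HTR1A, the serotonin autoreceptor, and the hormone-related genes ESR1, PGR and FKBP5 were too dim to be tested, with mean log2 intensities of 5.07, 4.97, 2.81 and 4.21 beside a highest mean of 5.6 among 30 control probe sets for transcripts that were not added. No probe set carried the name of SLC6A4 or MAOB in the gene table used. Of the 8 measured genes of serotonin synthesis, transport and breakdown, 7 were higher under estrogen, 5 under estrogen plus progesterone and 2 under progesterone, with limma camera adjusted p of 0.368, 0.804 and 0.503. The adjusted p with an estimated correlation was 0.713, 0.870 and 0.857, and 0 members passed when adjusted over the list alone.

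**Figure D2:**
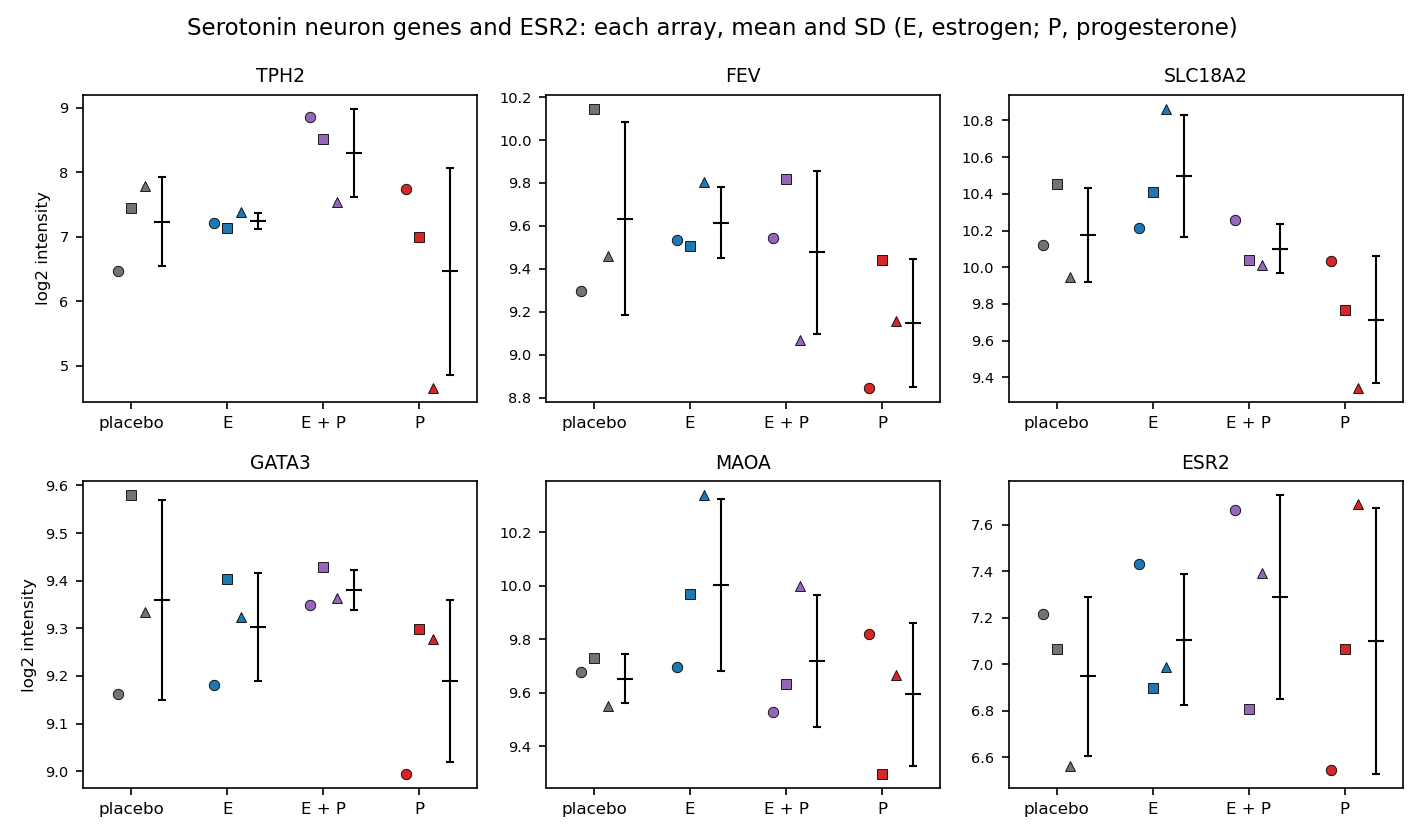
Log2 intensity of 5 genes of the serotonin system and of ESR2 in each of the 12 arrays, with the mean and SD of each group of 3 (E, estrogen; P, progesterone). TPH2 ranges from 4.66 in the third progesterone array to 8.85 in an array of the combined treatment.

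The comparison of estrogen with placebo asked what estrogen alone does. The nearest named gene to passing was CNTNAP2, a neuronal cell adhesion molecule of the neurexin family, at a log2 difference of 1.36 ± 0.23 (SE, n = 3 per group) and a fold of 2.56. Other genes with higher values in all 3 estrogen arrays were TOB2 (1.87), an antiproliferative protein, TMEM171 (0.99), PROZ (0.997), LRRTM1 (0.86), a synaptic adhesion protein, CA8 (0.74), abundant in cerebellar Purkinje cells, C5H4orf33 (0.69), PSMC4 (0.59), a proteasome subunit, P3H1 (0.51), a collagen prolyl hydroxylase, and MAN1A2 (0.50), a Golgi mannosidase. Genes with lower values in all 3 were TMEM106B (-1.75), a lysosomal membrane protein, TNFAIP6 (-1.11), a hyaluronan-binding protein, CEP89 (-0.82), MAMU-E (-0.79), a class I histocompatibility gene, PATE4 (-0.72), LLGL1 (-0.70), a cell polarity protein, ARHGAP18 (-0.69), CPQ (-0.66), NCAM1 (-0.58), the neural cell adhesion molecule, and RHOQ (-0.55). None of these 20 passed the test: limma called 0 of 26383 probe sets, with a lowest adjusted p of 0.9997 and 699 at an unadjusted p under 0.05, where 1319 would be expected by chance. The 3 estrogen arrays lay above all placebo arrays for 939 probe sets and below them for 1050, together 7.54%, where chance gives 10%.

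Camera called 2 gene lists in this comparison, in opposite directions, and neither call held with an estimated correlation. The list of cerebellar neuron markers was higher under estrogen in 5 of 5 measured genes (median log2 difference 0.56, camera adjusted p = 0.00376), and the 4 genes with the lowest p were CA8 (0.74 ± 0.19, SE), ZIC2 (0.64 ± 0.45), CBLN3 (0.56 ± 0.42) and ITPR1 (0.33 ± 0.31), which code for a calcium-signalling regulator, a transcription factor of granule cells, a granule cell secreted protein and the inositol trisphosphate receptor of Purkinje cells. Of these, 1 gene, CA8, passed when adjusted over the list alone and 0 over all probe sets. The oligodendrocyte and myelin list was lower in 10 of 12 genes (median -0.21, adjusted p = 0.0356), among them MYRF (-0.49 ± 0.19), the transcription factor of myelination, MAL (-0.39 ± 0.28), PLLP (-0.31 ± 0.24) and ENPP2 (-0.23 ± 0.18), with 0 genes past the threshold over the list alone. The adjusted p of each list with an estimated correlation was 0.603. The second estrogen array decided both: it held the highest value of the 6 arrays for all 5 cerebellar genes and the lowest for 11 of 12 myelin genes, and without it the medians were 0.15 (adjusted p = 0.392) and -0.04 (adjusted p = 0.610). Without the third placebo array the cerebellar call ended (0.0516), and leaving out any 1 of the 3 placebo arrays ended the myelin call (0.298, 0.0544 and 0.0573).

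Estrogen plus progesterone against placebo asked what the combined treatment does. CNTNAP2 again had the lowest p among the higher genes (1.35 ± 0.23, SE, n = 3 per group). It was followed by BCAT1 (0.90), which starts the breakdown of branched-chain amino acids, EIF2D (0.70), a translation factor, ALDH6A1 (1.31), a mitochondrial enzyme of valine breakdown, KALRN (0.98), a regulator of dendritic spines, TMEM33 (0.94), CHST12 (0.62), a chondroitin sulfotransferase, UBAP1L (1.17), POLL (0.66), a repair DNA polymerase, and MMP28 (0.63), a matrix metalloproteinase. Lower in all 3 arrays were PLXDC2 (-1.64), NUP160 (-1.44), a nuclear pore protein, SRPX (-1.42), NOP9 (-1.12), MPZL2 (-0.91), TMEM64 (-0.90), KCNS3 (-0.85), a potassium channel subunit, SAR1B (-0.85), a GTPase of export from the endoplasmic reticulum, TMEM150A (-0.80) and DUSP1 (-0.63), a phosphatase of MAP kinases. None of these 20 genes passed the test: limma called 0 probe sets, with a lowest adjusted p of 0.9988 and 1017 at an unadjusted p under 0.05. The arrays lay outside the placebo range for 1234 probe sets upward and 1540 downward, 10.5% in all beside 10% by chance. Of the 35 gene lists, camera called 0, with 1 at an unadjusted p under 0.05: the microglia and macrophage list was lower in 11 of 15 genes (median -0.14, adjusted p = 0.638).

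In the reported fit, progesterone alone against placebo gave more probe sets past the threshold (35) than any other comparison. The order turned in some other fits: without the first placebo array it gave 10, beside 42 for estrogen plus progesterone against progesterone. PPP2R2C, a regulatory subunit of protein phosphatase 2A made mainly in brain, rose 12-fold (log2 3.59 ± 0.49, SE, n = 3 per group, adjusted p = 0.0180), and by a log2 of 2.85 (adjusted p = 0.00492) without the first placebo array. That array stood at 5.28 beside 7.29 and 7.72 in the other 2. PPM1A, another serine/threonine phosphatase, rose by 2.18 ± 0.24 (adjusted p = 0.00735), the chromatin regulator ANKRD11 by 1.96 ± 0.21 (0.00735) and the membrane protein TM7SF3 by 1.90 ± 0.19 (0.00735). Also higher were CCDC88A (2.01), an actin-binding protein of cell migration, ITPRID2 (1.94), SREK1 (1.86), a splicing regulator, MYO6 (1.80), a motor of vesicle traffic, WASHC4 (1.72), a subunit of the endosomal WASH complex, and GPBP1 (1.52), a transcription factor, with adjusted p from 0.0166 to 0.0407. The genes that fell were SFPQ (-1.41 ± 0.20, adjusted p = 0.0253), a nuclear RNA-binding protein of splicing and paraspeckles, LPCAT4 (-1.09 ± 0.16, 0.0307), an enzyme of phospholipid remodelling, and CD47 (-1.05 ± 0.16, 0.0381), a surface protein that restrains phagocytosis. These 13 genes were those that the rule for named genes took. The lower genes nearest to passing were YPEL5 (-1.08, adjusted p = 0.0512), KCTD6 (-0.99), ELFN2 (-1.08), MRPL30 (-1.44), a mitochondrial ribosomal protein, EXOC3L1 (-0.84), DCLK2 (-1.04), a neuronal microtubule-associated kinase, and ZNF41 (-1.01), with adjusted p from 0.0912 to 0.107 after YPEL5.

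**Figure D3:**
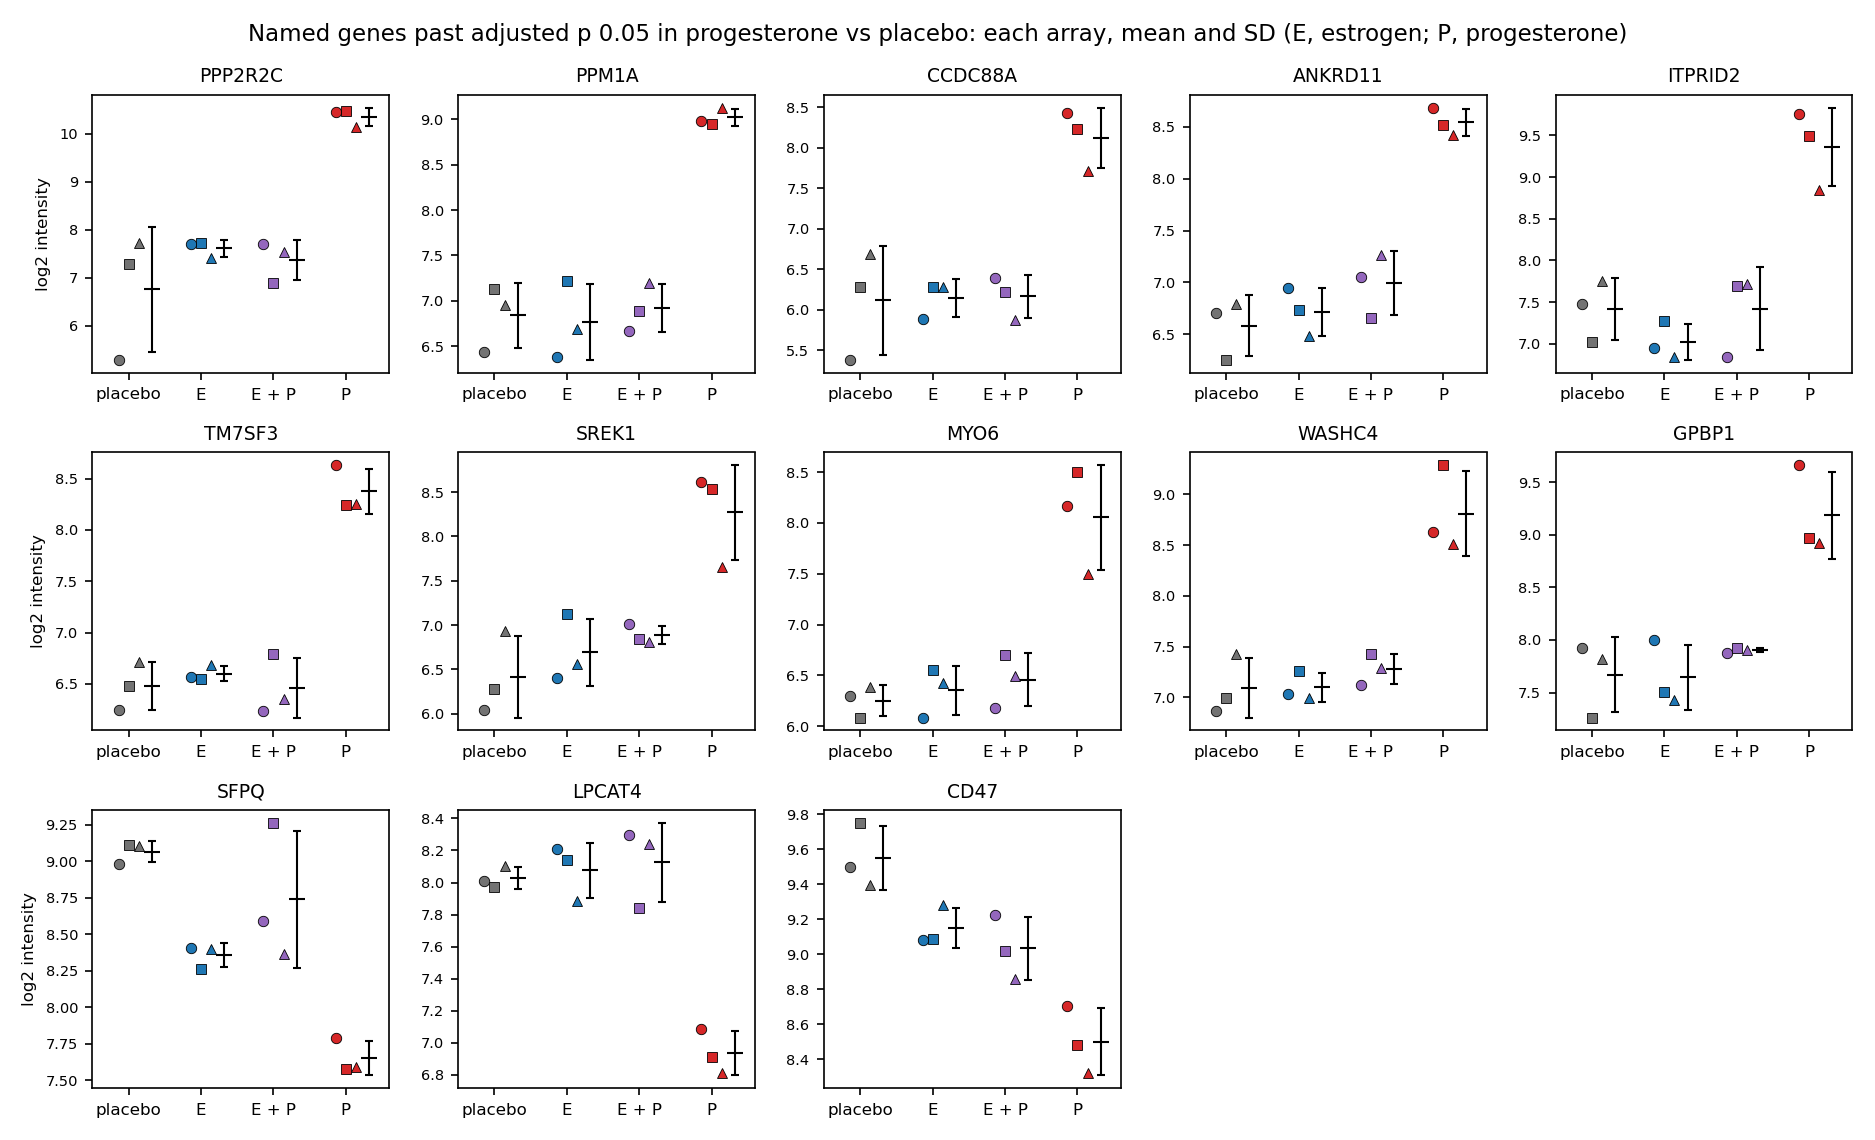
Log2 intensity of the 13 named genes past the threshold in progesterone against placebo, with 1 point per array and the mean and SD of each group of 3 (E, estrogen; P, progesterone). The 3 progesterone arrays lie apart from the 3 placebo arrays in every panel, and PPP2R2C averages 10.35 under progesterone, 6.76 under placebo, 7.61 under estrogen and 7.37 under the combined treatment.

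In all, limma called 35 probe sets in this comparison, 31 higher and 4 lower, for 15 named genes (the others were USP16, 1.52, a histone deubiquitinase, and EXTL2, 1.11, a glycosyltransferase) and 18 probe sets without a name, with 2605 at an unadjusted p under 0.05 (1250 higher, 1355 lower). Without the first progesterone array the calls were 25, of which 16 were higher and 9 lower. The progesterone arrays lay above all placebo arrays for 1956 probe sets and below them for 2075, 15.3% beside 10% by chance. PPP2R2C and WASHC4 were called on 2 probe sets each. The 15 genes had 28 other probe sets, those that did not pass, of which 21 went the same way. The median change of these in the direction of the call was 0.19 (SD 0.54), with a range from -0.50 (CCDC88A) to 1.64 (CD47); USP16 (1.59, adjusted p = 0.0862), WASHC4 (1.44) and GPBP1 (0.88) followed CD47. With only the brightest probe set of each gene tested, which left 1 of the 35 in the test, 0 were called, and with only the 6 arrays of these groups in the fit 0 were called. The count was 10 without the first placebo array, 5 without the second, 55 without the third, 7 without the second progesterone array, 19 without the third, 21 without the third array of the combined treatment, and 13 without the 3 arrays apart on the first component. PPM1A, ANKRD11 and TM7SF3 stayed past the threshold in all 12 fits that left out 1 array, while CCDC88A stayed in 3, GPBP1 in 1, CD47 in 3, SFPQ in 6, PPP2R2C and MYO6 in 8, WASHC4 in 9, and ITPRID2, SREK1 and LPCAT4 in 4.

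None of the 35 gene lists passed in progesterone against placebo, where camera had 3 at an unadjusted p under 0.05. The ependyma and choroid plexus list was lower in 7 of 7 genes (median -0.34, adjusted p = 0.243), the synaptic vesicle release list in 10 of 11 (median -0.16, adjusted p = 0.410), and the GABA and glycine receptor list was higher in 7 of 9 (median 0.16, adjusted p = 0.410). The 13 measured genes known to respond to progestins and corticosteroids were higher in 8 (median 0.09, adjusted p = 0.784), and the 7 markers of serotonin neuron identity were lower in 6 (median -0.17, adjusted p = 0.503). Among these, SLC18A2, the vesicular monoamine transporter, differed by -0.46 and FEV, the transcription factor of serotonin neurons, by -0.49. With an estimated correlation the adjusted p of each of these 5 lists was 0.857.

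**Figure D4:**
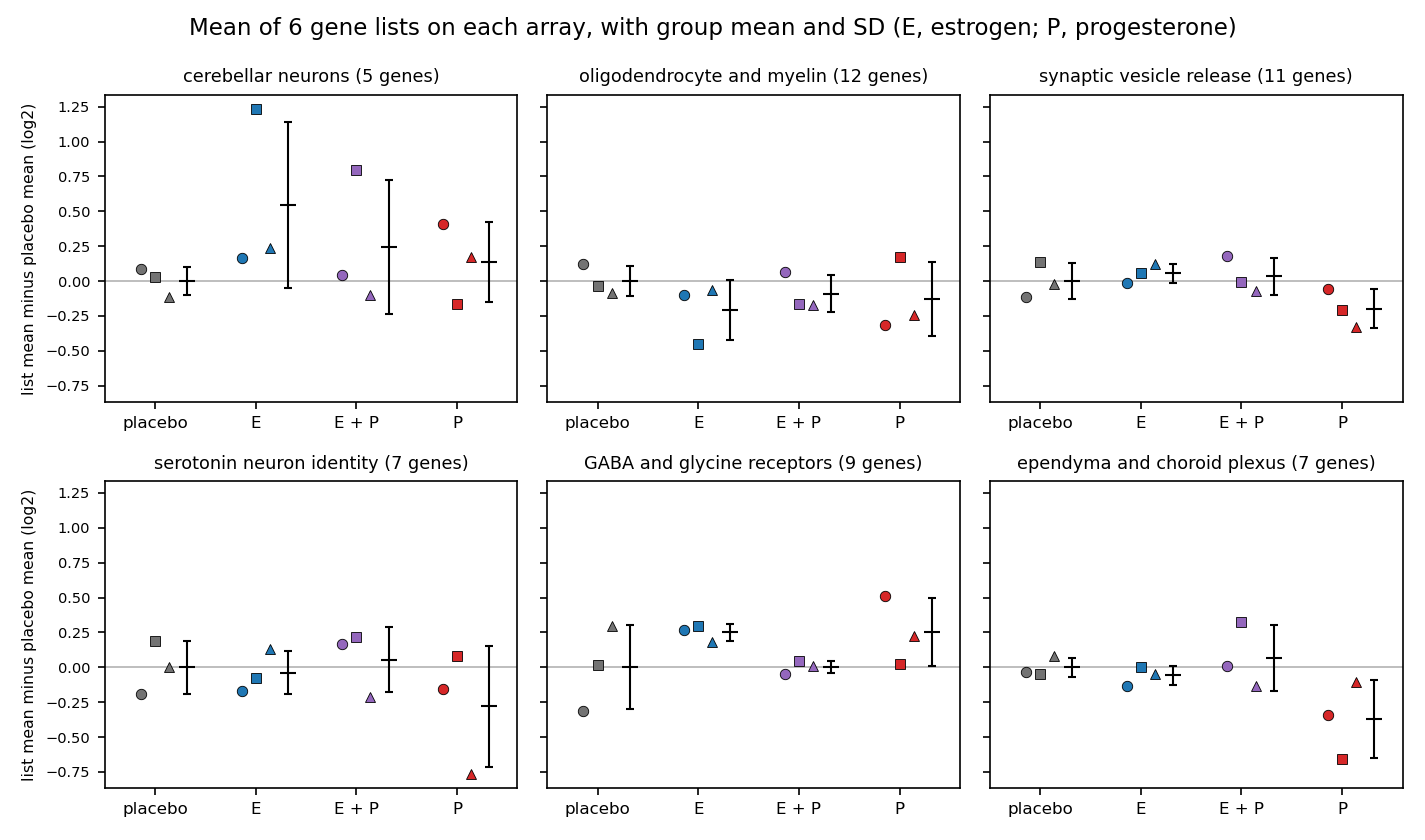
Mean log2 difference of 6 gene lists from their placebo mean in every array, with 1 point per array and the mean and SD of each group of 3 (E, estrogen; P, progesterone). The cerebellar list stands at 1.23 in the second estrogen array and at 0.79 in the second array of the combined treatment.

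Estrogen plus progesterone against progesterone asked what adding estrogen to progesterone does. Several genes that had risen under progesterone were lower with estrogen present: PPM1A fell by 2.11 ± 0.24 (log2, SE, n = 3 per group, adjusted p = 0.0113), TM7SF3 by 1.92 ± 0.19 (0.0103) and a further probe set of WASHC4 changed by -2.24 ± 0.26 (0.0113). USP16 fell by 1.59 and EXTL2 by 1.22, both with an adjusted p of 0.0182. Higher with estrogen were ELFN2, a synaptic leucine-rich repeat protein (1.59 ± 0.21, adjusted p = 0.0182), LPCAT4 (1.19 ± 0.16, 0.0217) and EXOC3L1 (1.09 ± 0.17, 0.0463). PPM1K, a mitochondrial phosphatase of branched-chain amino acid breakdown, at 1.46, and CCDC181, at 1.19, did not pass (adjusted p = 0.0807 and 0.0905). In total limma called 22 probe sets, 4 higher and 18 lower, for 11 named genes, with 3010 at an unadjusted p under 0.05 (1592 higher, 1418 lower). Of the 22, 18 were among the 35 of progesterone against placebo, all with the opposite sign, 17 of them higher in the progesterone arrays. Both comparisons use those arrays, so some sharing follows from the design. In 100 random regroupings of the arrays a median of 0 and at most 26 were shared. A regrouping with few calls can share only few, so this median does not measure how much sharing the common arrays bring.

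The count of 22 rested on single arrays. It was 0 without the second progesterone array, 7 without the third, 36 (19 higher, 17 lower) without the first, 3 without the first or the second array of the combined treatment, 13 without the third of these, 42 without the first placebo array and 14 without the second. TM7SF3 stayed past the threshold in 11 of the 12 such fits, WASHC4 and EXTL2 in 9, PPM1A and USP16 in 8, ELFN2 in 7, LPCAT4 in 5 and EXOC3L1 in 2, and with only the brightest probe set of each gene 0 were called.

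Estrogen plus progesterone against estrogen asked what progesterone adds once estrogen is present. CEP89, a centrosomal protein, was higher by 1.23 ± 0.21 (log2, SE, n = 3 per group), UBAP1L by 1.46 ± 0.31, LLGL1 by 0.81 ± 0.17, STX5, a Golgi SNARE protein, by 0.61 ± 0.15 and TAPBP, which loads peptides on histocompatibility proteins, by 0.57 ± 0.14. NUP160 was lower (-1.21 ± 0.26), as were AMACR (-1.0003 ± 0.22), a peroxisomal racemase, HACD1 (-0.82 ± 0.19), KCNS3 (-0.78 ± 0.17) and DAB2 (-0.69 ± 0.15), an endocytic adaptor. None passed: limma called 0 probe sets with 786 at an unadjusted p under 0.05, and the lowest adjusted p was 0.9999. The 35 probe sets called under progesterone alone had a median change of 0.12 (SD 0.30) here in the direction of that call, with 22 of 35 going the same way, against 1.90 (SD 0.65) in progesterone against placebo.

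Across the 6 arrays with estrogen and the 6 without, no probe set passed. Of the genes with the lowest p, EXOC3L1 (0.75 ± 0.12, SE), ELFN2 (0.93 ± 0.15), LPCAT4 (0.62 ± 0.12), SIRT6 (1.60 ± 0.27), a histone deacetylase, and CNTNAP2 (0.94 ± 0.16) were higher with estrogen. WASHC4 (-1.34 ± 0.18), TM7SF3 (-0.90 ± 0.13), PPM1A (-1.09 ± 0.17), EXTL2 (-0.63 ± 0.11) and ITPRID2 (-1.17 ± 0.21) were lower. In these lower genes the progesterone arrays lay above all other arrays. TM7SF3 stood at 8.25 to 8.63 there and at 6.24 to 6.79 in the placebo, estrogen and combined arrays. EXOC3L1, ELFN2 and LPCAT4 were in turn lowest in the progesterone arrays. For all of these genes the contrast does not show a change under estrogen alone. SIRT6 and CNTNAP2 were not split that way. Limma made 0 calls, with a lowest adjusted p of 0.116 and 2014 probe sets at an unadjusted p under 0.05. The synaptic vesicle release list was higher with estrogen in 10 of 11 genes (median 0.18, camera adjusted p = 0.0340). The 4 genes with the lowest p were CPLX2 (0.50 ± 0.10), a complexin that controls vesicle fusion, STX1A (0.36 ± 0.15), SV2B (0.28 ± 0.13) and RAB3A (0.18 ± 0.10). With an estimated correlation its adjusted p was 0.652, so the call did not hold, and of its members 1, CPLX2, passed when adjusted over the list alone and 0 over all probe sets. CPLX2 had a mean log2 intensity of 9.87 ± 0.07 (SD) under progesterone, 10.54 ± 0.15 under placebo, 10.80 ± 0.08 under estrogen and 10.62 ± 0.16 under both. The mean of the whole list, relative to placebo, was -0.33 to -0.06 in the progesterone arrays. It was -0.02 to 0.12 in the estrogen arrays and -0.07 to 0.18 in the combined arrays, beside -0.11 to 0.14 in the placebo arrays themselves. The difference thus lay largely in low values under progesterone alone. The list's adjusted p was 0.552 without the first placebo array and 0.544 without the 3 arrays apart, and it was above the threshold in 8 of the 12 fits that left out 1 array.

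Across the 6 arrays with progesterone and the 6 without, ANKRD11 (1.12 ± 0.15, SE, adjusted p = 0.0783), PPM1A (1.17 ± 0.17), TM7SF3 (0.88 ± 0.13), UBAP1L (1.35 ± 0.22) and WASHC4 (0.95 ± 0.16) were higher. CASD1 (-0.79 ± 0.15), a sialic acid acetyltransferase, KCNS3 (-0.65 ± 0.12), CD47 (-0.58 ± 0.12), NUP160 (-0.93 ± 0.19) and FAM216A (-0.63 ± 0.13) were lower. Nothing passed: limma called 0 probe sets, with 1650 at an unadjusted p under 0.05, and camera called 0 lists, with 1 at an unadjusted p under 0.05 and a lowest adjusted p of 0.556.

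The interaction asked whether the response to progesterone depends on estrogen. TM7SF3 (-2.04 ± 0.27, SE), PPM1A (-2.03 ± 0.34), ANKRD11 (-1.69 ± 0.29), USP16 (-1.68 ± 0.29) and PPP2R2C (-3.83 ± 0.69) had the lowest p among genes with a negative interaction. SFPQ (1.80 ± 0.29), LLGL1 (1.26 ± 0.25), CCDC181 (1.495 ± 0.30), LPCAT4 (1.14 ± 0.23) and YPEL5 (1.17 ± 0.26) had the lowest p among those with a positive one. No probe set passed this test of the difference itself (0 by limma, lowest adjusted p = 0.211, 1688 at an unadjusted p under 0.05), whose 95% confidence interval extended a median of 0.69 to each side. The F test for any difference among the 4 groups called 20 probe sets, for 9 named genes and 10 without a name, with 1988 at an unadjusted p under 0.05. Its lowest p belonged to TM7SF3, PPM1A, ANKRD11 and WASHC4 (adjusted p = 0.0114) and to EXTL2 (0.0299). The F count was 0 without the second or the third progesterone array, 9 without the first, 10 without the second placebo array, 8 without the third estrogen array and 13 without the first array of the combined treatment.

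The correlations between fold changes of the comparisons with placebo, which share the placebo arrays, lay inside the range of random regroupings. Across probe sets, which are not independent replicates, the correlation was 0.57 between estrogen and estrogen plus progesterone, 0.42 between estrogen and progesterone, and 0.40 between estrogen plus progesterone and progesterone. In 100 random regroupings of the 12 arrays the medians were 0.53, 0.52 and 0.52, and 32, 72 and 75 of them gave values as high. The covariances were below the regrouped medians, by -0.00534, -0.00621 and -0.00203. In 100 regroupings within each replicate number, which give every group 1 array of each number, the median correlations were 0.48, 0.47 and 0.48, and 23, 69 and 73 gave values as high. Against these the covariances were above the medians, by 0.00200, 0.00184 and 0.00126, and 45, 48 and 44 regroupings gave covariances as high.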

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

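All tests of explanations in this part were chosen only after the result was seen, except the counts of other splits of the arrays and the test of the nuclear RNA list.

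The 35 probe sets called in progesterone against placebo, PPP2R2C, PPM1A, ANKRD11 and TM7SF3 among them, stood apart in the 3 progesterone arrays and not in the arrays with both hormones. Their median change in estrogen plus progesterone against estrogen was 0.12 (SD 0.30) against 1.90 under progesterone alone. For these probe sets that argues against a progesterone response of the latter size that does not depend on estrogen. A smaller one is not excluded, since the 35 were chosen for their large change under progesterone. The SD is over probe sets, not animals. Quantile normalization as the whole source was excluded, since under median alignment 24 of the 35 stayed past the threshold and all 35 kept their direction. RNA quality or array processing that differed for the progesterone arrays cannot be told apart from the treatment. In 1 of 7 control measures, the EF1A 3′ minus 5′ signal, all 3 progesterone arrays lay outside the range of the other 9. That signal was lower, at a mean of -0.34 beside 0.20 (two-sided exact permutation p = 0.0273, adjusted p = 0.0875 over the 7). The actin 3′ minus 5′ signal was higher, at 0.95 beside 0.53 (two-sided exact permutation p = 0.00909, adjusted 0.0636). The GAPDH 3′ minus 5′ signal was lower, at 0.34 beside 0.59 (two-sided exact permutation p = 0.159, adjusted 0.223). The cre and bioB controls were lower (two-sided exact permutation p = 0.0455 and 0.050, adjusted 0.0875). The 3′ minus 5′ signals thus did not all go the same way. The progesterone group holds no other arrays to compare within. More nuclear or unspliced RNA in these arrays cannot be told apart either: the list of nuclear RNA and splicing factor transcripts had a median of 0.13, higher in 15 of 24 genes, with a camera p of 0.0276 at the preset and 0.109 with an estimated correlation, and the estrogen arrays, where 0 probe sets were called (699 at an unadjusted limma p under 0.05), gave p = 0.0250 at the preset. A progesterone response that estrogen blocks remains open as a hypothesis; its own test, the interaction, called 0 probe sets by limma (1688 at an unadjusted p under 0.05).

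The first arrays of the placebo, estrogen and estrogen plus progesterone groups stood apart from the other 9 on the first principal component. Hormone treatment was excluded as the source, because each of them lay at least 56.2 from the other arrays of its own group while the other 9 spanned 30.7. Labelling or hybridization strength cannot be told apart from other sources: 2 of the 3 had spiked control signals above those of the other 9 (10.79 and 10.98, where the 9 reached 10.3), and the third, at 10.2, lay inside their range. The same 2, the first estrogen and combined arrays, had the highest EF1A 3′ minus 5′ signals (0.74 and 0.65, where the 9 reached 0.22). The first placebo array, at -0.03, again lay inside the range. RNA quality was not tested as a source. Cell type composition of the block stays open too, since 1 of 14 cell type lists, GABA and glycine neurons, had all 3 arrays outside the other 9, and 26 of the 220 sets of 3 arrays gave at least as many.

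The cerebellar list was higher in estrogen against placebo. The values are consistent with cerebellar tissue in the block of the second estrogen array, which held the highest value of the 6 arrays for all 5 genes of the list; the dim cerebellar genes FAT2 (7.61) and PCP2 (7.15), too dim to be tested, were highest there as well. CBLN3 reached 9.45 and CBLN1 9.11 in that array, and 8.52 and 8.52 in the second array of the combined treatment. All 5 genes of the list were also above the filter level of 6.31 in the mean of the placebo arrays, so their presence alone does not mark cerebellum. An estrogen response in every animal cannot be told apart from none with the 2 remaining estrogen arrays, whose median was 0.15 (adjusted p = 0.392).

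Other splits of the arrays give counts to set beside the real ones. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For progesterone against placebo 1 of the 10 splits, the real one, reached 35 probe sets and the highest other gave 6; for estrogen plus progesterone against progesterone 1 reached 22 and the highest other gave 1. Estrogen, estrogen plus progesterone, and estrogen plus progesterone against estrogen had a real count of 0 by limma (699, 1017 and 786 at an unadjusted p under 0.05), which all 10 splits reached, as any split must, with highest others of 1, 0 and 0. For the second and the last of these that includes the splits that part as many same-numbered pairs as the real one. For lists, 2 of 10 splits reached the 2 of estrogen against placebo (highest other 2), and all 10 reached the 0 of camera in estrogen plus progesterone and in progesterone (1 and 3 at an unadjusted p under 0.05), with highest others of 1 and 7. Among 100 splits of all 12 arrays, the probe set counts of the main effects and the interaction could not be tested against chance. They were 0 for estrogen, progesterone and the interaction by limma (2014, 1650 and 1688 at an unadjusted p under 0.05), which any split reaches. The highest others were 151, 499 and 7. For lists 42 reached the 1 list of the estrogen main effect (highest other 5), so chance could not be excluded for it. The progesterone main effect had 0 lists by camera (1 at an unadjusted p under 0.05), which any split reaches (highest other 6). For the F test 4 of 100 splits reached 20 probe sets, a share narrowly under 0.05. These splits ignored the replicate numbers, which were taken to pair some of the groups, so chance is not excluded by this share. The evidence is weak: the F count was 1 of 14 counts set beside splits, without adjustment, the highest other split gave 260, and the count was 0 without the second or the third progesterone array. Which arrays the splits with the highest counts brought together was not examined, so the cause of those counts was not tested.

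For the GABA and glycine receptor list camera called the interaction (median -0.39, lower in 9 of 9 genes, adjusted p = 0.0379), a call that held neither with an estimated correlation (0.967) nor by fry (0.767). For the microglia and macrophage list the interaction median was also -0.39 (lower in 13 of 15 genes, adjusted p = 0.0379, and 0.967 with an estimated correlation and 0.802 by fry). In the ependyma and choroid plexus list it was 0.39 (higher in 7 of 7 genes, adjusted p = 0.0379, and 0.967 with an estimated correlation and 0.767 by fry). Among the array controls, which the comparisons do not use, all 3 estrogen arrays exceeded all 3 placebo arrays in the EF1A 3′ minus 5′ signal, by 0.34 on average. All 3 progesterone arrays exceeded the placebo arrays in the actin 3′ minus 5′ signal, by 0.58 on average. Of 21 such comparisons 2 were found, where chance gives 5% each, or 1.05. All 3 progesterone arrays also lay below the placebo arrays in EF1A 3′ minus 5′, bioB and cre, so that in either direction there were 5 of 21, 4 of them in the progesterone group, beside 2.1 by chance; the measures are not independent.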

How the results depend on the processing

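Leaving out the 3 arrays that stand apart on the first component, fitting them as a block, and fitting the 9 arrays without the progesterone group with and without the replicate block, were chosen only after the result was seen. All other alternatives were planned. Of 1661 values of the 130 named results under an alternative, 1484 kept their direction and side of the threshold, 103 fell short of it in the same direction, 14 came to pass it and 60 changed sign. Most of the 130 had not passed in the reported fit and count as kept when they again did not pass. The 103 come only from the few results that had passed, so the 1484 do not measure how well calls held. Of the fits without 1 array, only the lowest and highest value of each result were counted. The 35 probe sets of progesterone against placebo kept their direction under every alternative that tested them. The number past the threshold was 24 with median alignment, 11 without a filter, 11 of the 11 tested at the 75th percentile, 35 with the higher floor, 35 with trend and robust variances, 33 with array weights, 19 with the replicate block, 18 with the myelin covariate, 9 without the 3 arrays apart, 34 with them as a block, 0 of the 1 tested with 1 probe set per gene and 0 with only the 2 groups compared. Signal over background limits what could be seen: HTR1A, ESR1, PGR and FKBP5 lay below the highest mean of the controls for transcripts that were not added (5.6). However, HTR1A (5.07), ESR1 (4.97) and FKBP5 (4.21) lay above their median of 3.09, and HTR1A reached 6.52 in 1 array. By the limit of 0.1 the replicate numbers were taken to pair estrogen plus progesterone with placebo and with estrogen, but no other groups compared. Of the same-numbered pairs of placebo and estrogen 1 of 3 exceeded 0.1, and 0 of 3 of each pairing with progesterone did. Passing the limit does not show pairing by number, since some unlike-numbered pairs passed it too. The third estrogen array and the second array of the combined treatment correlated by 0.267. Of 12 arrays, 5 correlated best with their own number. In the 9 arrays without the progesterone group limma called 0 probe sets in estrogen, in estrogen plus progesterone and between them (738, 1055 and 894 at an unadjusted p under 0.05), and 0 with the replicate block as well (1165, 1637 and 1375). Where a fit without 1 array leaves 2 in a group, the spread is pooled over all groups.

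Leaving out 1 array in turn gave ranges of 0 to 1 probe sets for estrogen, 0 to 1 for estrogen plus progesterone, 5 (without the second placebo array) to 55 (without the third) for progesterone, 0 to 1 for estrogen plus progesterone against estrogen, 0 (without the second progesterone array) to 42 (without the first placebo array) for estrogen plus progesterone against progesterone, 0 to 1 for the estrogen main effect, 0 to 7 for the progesterone main effect, 0 to 4 for the interaction and 0 to 25 for the F test. For lists it gave 0 to 2 for estrogen, 0 for estrogen plus progesterone, 0 to 1 for progesterone, 0 to 2 for the estrogen main effect and 0 for the progesterone main effect. The correlations of fold changes ranged from 0.43 to 0.74, 0.33 to 0.60 and 0.31 to 0.59.

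For the counts that moved by over 1.5 times the cause was not tested, except where fewer probe sets or arrays were used. Median alignment gave 13 probe sets for the F test, 1 list for estrogen and 2 lists for the estrogen main effect. No filter gave 1 probe set for estrogen and 1 for estrogen plus progesterone. The 75th percentile gave 4 for estrogen plus progesterone against progesterone, 4 for the F test, 1 list for estrogen and 0 lists for the estrogen main effect. Trend and robust variances gave 66 (55 higher, 11 lower) for progesterone, 42 for estrogen plus progesterone against progesterone and 36 for the F test. Array weights gave 44 for estrogen plus progesterone against progesterone, 6 for the estrogen and 1 for the progesterone main effect, and 0 lists for the estrogen main effect. The replicate block gave 20 (20 higher, 0 lower) for progesterone, 2 for the progesterone main effect and 1 list for estrogen, where the myelin list had an adjusted p of 0.0563. It moved no other count of calls by over 1.5 times. The myelin covariate gave 20 for progesterone, 10 for the F test, 0 lists for estrogen, 1 for progesterone and 0 for the estrogen main effect. This covariate is the mean of the myelin list itself, so the loss of that list for estrogen was fixed in advance. The cerebellar list had a camera adjusted p of 0.334 with it. Without the 3 arrays apart there were 13 (11 higher, 2 lower) for progesterone, 1 list for estrogen, 1 for progesterone and 0 for the estrogen main effect. With them as a block there were 64 for progesterone, 47 for estrogen plus progesterone against progesterone, 3, 4 and 1 for the estrogen and progesterone main effects and the interaction, and 2 lists for the estrogen main effect. With 1 probe set per gene there were 0 for progesterone, for estrogen plus progesterone against progesterone and for the F test; with only the 2 groups compared there were 0 for progesterone and 7 for estrogen plus progesterone against progesterone. An estimated correlation and fry each gave 0 lists for estrogen and for the estrogen main effect.

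On another probe set of the same gene the log2 change had the other sign for the genes that follow, none past the threshold on that probe set, and the cause was not tested. In estrogen against placebo these were CNTNAP2 (-0.15 and -0.047), TOB2 (-0.14 and -0.070), PROZ (-0.065), MAN1A2 (-0.22), PSMC4 (-0.20), NCAM1 (0.042, 0.13, 0.027 and 0.0064), CPQ (0.0073), ARHGAP18 (0.13), RHOQ (0.034), MYRF (0.0064) and ITPR1 (-0.054). In estrogen plus progesterone against placebo these were CNTNAP2 (-0.22), BCAT1 (-0.17), TMEM33 (-0.18 and -0.067), CHST12 (-0.074), SAR1B (0.0059 and 0.087), NOP9 (0.0048, 0.13 and 0.085) and MAOA (-0.015 and -0.058). In progesterone against placebo these were PPP2R2C (-0.073), CCDC88A (-0.50, -0.33 and -0.20), ANKRD11 (-0.44), SREK1 (-0.095), EXTL2 (-0.030) and KCTD6 (0.095). In estrogen plus progesterone against estrogen these were LLGL1 (-0.15), DAB2 (0.023) and HACD1 (0.055). In estrogen plus progesterone against progesterone these were CCDC181 (-0.83) and USP16 (0.18). In the estrogen main effect these were CNTNAP2 (-0.42), PPM1A (0.11) and EXTL2 (0.036). In the progesterone main effect these were ANKRD11 (-0.18), PPM1A (-0.065), WASHC4 (-0.092) and CD47 (0.024). In the interaction these were CCDC181 (-0.077 and -1.26), YPEL5 (-0.24), ANKRD11 (0.52) and PPP2R2C (0.31). TPH2 in estrogen against placebo was -0.18 with array weights and -0.36 without the 3 arrays apart. Leaving out 1 array in turn, TPH2 ranged from -0.37 to 0.29 in estrogen, from 0.68 to 1.45 in estrogen plus progesterone and from -1.41 to 0.13 in progesterone, ESR2 from -0.035 to 0.29 in estrogen, from 0.15 to 0.58 in estrogen plus progesterone and from -0.14 to 0.43 in progesterone, and MAOA from 0.18 to 0.50 in estrogen, from -0.073 to 0.16 in estrogen plus progesterone and from -0.17 to 0.090 in progesterone.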

Other observations

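The tests of the other probe sets and of single arrays in this part were chosen only after the result was seen.

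The third progesterone array was the lowest of the 12 in 6 of the 35 gene lists, not in serotonin neuron markers alone. The first placebo, first and second estrogen and second progesterone arrays were each lowest in 4. The 6 lists are not separate observations, since TPH2 and SLC18A2 are in both serotonin lists. The 7 measured genes of serotonin neuron identity averaged -0.77 (log2, relative to placebo) in the third progesterone array, the lowest of the 12, and between -0.22 and 0.21 in the other 11. It was also lowest there for glutamate receptors (-0.79, next -0.42), dopamine and noradrenaline neurons (-0.68, next -0.38), serotonin synthesis, transport and breakdown (-0.59, next -0.25), synaptic vesicle release (-0.33, next -0.21) and stress peptides (-0.23, next -0.18). TPH2 was 4.66 in that array and between 6.47 and 8.85 in the others, SLC18A2 was 9.34 beside 9.77 to 10.86, and GATA2, a transcription factor of the same neurons, was 6.71 beside 7.22 to 7.78. These 3 of the 7 were lowest there. The other 4 (FEV, GATA3, UCN and SLC17A8) lay inside the range of the other arrays. The microglia and macrophage list, which holds phagocyte and complement genes, was lowest in the third array of the combined treatment (-0.44) and highest in the second progesterone array (0.29). The ependyma and choroid plexus list was lowest in the second progesterone array (-0.66) and highest in the second array of the combined treatment (0.32).

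Whether the genes called under progesterone differ in all of their transcripts or in part could not be decided. If every transcript of each gene had changed, its other probe sets should have moved alike. The 28 other probe sets of the 15 named genes moved less. Their median change in the direction of the call was 0.19 (SD 0.54), against 1.86 for the probe sets called. A change of every transcript is not excluded by this. The called probe sets were chosen for passing and the other 28 for not passing. The other probe sets were also brighter, with a mean log2 intensity of 8.82 against 7.62. Another probe set of CD47 (1.64), USP16 (1.59) and WASHC4 (1.44) went by a like amount in the direction of the call without passing. PPP2R2C and WASHC4 were called on 2 probe sets each. Of the 35 called probe sets, 51.4% had no gene name, beside 38.7% of all tested. Which part of each transcript a probe set covers was not examined here.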
